A study of Mus musculus with 109 samples.

How the data were processed

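The analysis used the authors' deposited processed tables alone, 1 for each of the 26 comparisons, and samples were assigned to groups from the labels before the data were examined. Per the submitters' processing notes, base calls came from CASAVA 1.8.2, reads were aligned with TopHat2 to mouse genome mm10, and groups were compared with Cuffdiff. Per the labels' protocols, RNA was taken with TRIzol, adult brains having been frozen first, and polyA libraries were made with the TruSeq RNA v2 kit. This kit keeps no strand, so reads of overlapping or antisense genes cannot be told apart. Reads of paralogs and pseudogenes, such as Rps, Rpl, Atp5l and Gm genes, are uncertain in the same way. The versions of TopHat2, Cuffdiff and the gene annotation are not given in the sources used here.

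The authors' FPKM values are 1 per gene and group, computed by Cuffdiff from all libraries of the group and normalized by it before deposit. The log2 fold changes are those the authors deposited, knockout over wild type, and were recomputed from the FPKM values as a check. The score is the authors' deposited Cuffdiff test statistic and was not used as a result. The p-value and q-value of each gene are the authors' Cuffdiff values as deposited, the q-value being adjusted within 1 comparison. The columns hold the groups as value 1 and value 2, and the values themselves show which is wild type. Value 1 is nearly identical in the 12 files of each time that share a cohort (SD from the median file 1.35e-05 to 0.0515 log2 units in adults and 0.0207 to 0.0277 at E14.5), while value 2 differs between them (0.112 to 0.229 and 0.150 to 0.296). Value 1 was therefore taken as wild type, and the lacZ and target values were then read as a check.

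Among 26754 genes, 25861 were matched to GENCODE M21 by identifier, and 25831 of them (99.9%) overlap the annotated position. Tests are reported for genes Cuffdiff tested, 15759 to 16071 per comparison, with calls at q under 0.05. The genes named are the targets and fixed neighbours, called genes within 1 Mb, passing members of the fixed lists, sex-linked genes, genes called at both times or in 3 or more strains, and the most changed called genes of a comparison. These last are 5 in each direction, or 10 in the 4 comparisons with most calls, at 1 FPKM or more, without the target and unnamed gene models. Windows reached 1 Mb to each side of the annotated lncRNA and were tested with Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over 26 comparisons. Windows were also dealt to strains at random in 100000 resamples, one-sided. The 44 gene lists were fixed beforehand, and list medians of genes at 1 FPKM or more in either group were compared with 10000 random lists drawn from 20 expression bins. Overlaps between times used Fisher's exact test over genes tested at both. Correlations between strains were set beside simulated groups of unchanged genes drawn against a shared cohort, and covariances beside the wild-type variance the shared cohort gives. Genes called in 3 or more strains were set beside 1000 simulations of independent lists and 1000 of unchanged genes against a shared cohort of 14. The analysis ran in python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

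Self-tests used simulated fold changes on the expressed genes of 1 comparison. For a 15-gene list among the 13931 expressed genes of linc-Brn1a embryos, 3, 37, 86 and 100 percent of 100 simulations lay outside the central 95 percent at true shifts of 0, 0.1, 0.2 and 0.4 log2 units. The window test gave p under 0.05 in 0.5 percent of 200 simulations without planted calls and in 100 percent with 5 planted calls. A simulated shared cohort of 14 with knockout groups of 3 gave r of 0.18 where theory gives 0.176, over 15000 genes.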

Results

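RNA from whole mouse brain was sequenced in 13 knockout strains, each lacking 1 long noncoding RNA (lncRNA), in adults and in embryos (E14.5). The 109 libraries hold 75 knockout libraries in 26 groups, of which 21 groups have 3 libraries, 4 have 2 and 1 has 4. Each strain was compared at each time with a cohort of wild-type brains, which gives 26 comparisons. The strains come from a 129 by C57BL/6 cross, with 12 strains and a cohort of 14 wild-type libraries per time in the third backcross generation (N3), and Kantr with its own cohort of 3 per time in generation N2.5. The comparisons ask which genes change in the brain when a lncRNA locus is lost, and whether these lie near the locus or elsewhere in the genome. The tables use the names Haunt, Manr, linc-Brn1a, linc-Brn1b, linc-Cox2 and linc-Enc1 for the strains labelled Halr1, Mannr, Pantr1, Pantr2, Ptgs2os2 and lincenc1. They give 1 FPKM value per gene and group (fragments scaled by transcript length and library size) with Cuffdiff's p and q, so no spread between libraries is given, the depth of each library is unknown, and Cuffdiff's test is the measure of error throughout. A gene is said to have risen or fallen where q is under 0.05, and values are given in the order wild type to knockout.

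The targeted lncRNA was lower in the knockout in 14 of the 14 comparisons in which it was tested, and in 21 of all 26. linc-Brn1a, an antisense transcript on chromosome 1 (mm10, 42590771 to 42694825, minus strand) next to the neural transcription factor gene Pou3f3, fell from 61.3 to 0.457 FPKM in adults and was 159 to 0.0397 FPKM at E14.5 in the authors' deposited tables. Tug1, a conserved lncRNA on chromosome 11 (3639785 to 3649042), was 23.9 to 0.0727 FPKM in adults and fell from 43.8 to 0.0586 FPKM at E14.5, again from the authors' deposited tables. The authors' deposited tables list Kantr (chromosome X, 152298500 to 152327495), a transcript beside Kdm5c, at 14.1 to 0.0244 FPKM in adults, and at E14.5 it fell from 7.52 FPKM to a value listed at 0. Crnde (chromosome 8, 92326038 to 92356120), beside Irx5, fell from 12.7 to 1.98 FPKM at E14.5 in the authors' deposited table, so part of its signal stayed. Haunt (chromosome 6, 52102949 to 52112532), at the edge of the Hoxa cluster, went from 1.75 FPKM to a value listed at 0 at E14.5, and Eldr (chromosome 11, 16935154 to 16951282), beside Egfr, was 4.37 to 0.0208 FPKM there, per the authors' deposited tables. Celrr (chromosome 1, 121087405 to 121120956) was 1.17 to 0.00646 FPKM in adults and 0.389 to 0.164 FPKM at E14.5, and linc-Brn1b (chromosome 1, 42707061 to 42713454) was listed at 0 in both knockout groups against 1.24 and 2.35 FPKM in wild type, as the authors' deposited tables give them.

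The authors' Cuffdiff test passed for 5 of the 14 tested targets, which are linc-Brn1a in adults (q = 0.0130), and Crnde (q = 0.0139), Haunt (q = 0.0266), Kantr (q = 0.00263) and Tug1 (q = 0.0398) at E14.5. It gave q = 0.999 to adult Kantr and q = 0.158 to embryonic linc-Brn1a in the authors' deposited tables, although both were near 0 in the knockout, so a large q of this test does not show that a gene kept its level. Manr (chromosome 3, 29891017 to 29924191), Peril (chromosome 3, 34764169 to 34782346), linc-Enc1 (chromosome 13, 97452053 to 97482622), linc-Cox2 (chromosome 1, 150159043 to 150164948) and Trp53cor1 (chromosome 17, 29057474 to 29078961) were too low in whole brain to be tested. Their wild-type values ran from 0.00789 FPKM for Peril to 0.193 FPKM for Trp53cor1, both adult, in the authors' deposited tables, and such trace levels do not check the knockout labels. In 5 comparisons, those of Peril and linc-Enc1 at both times and of Manr at E14.5, the trace value was higher in the knockout group.

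The tables also hold a row for lacZ, the bacterial reporter gene, which serves as a second check of the labels. In the authors' deposited tables lacZ was between 0.00332 and 0.00821 FPKM in wild type and between 0.0660 and 43.6 FPKM in the knockout groups. Its highest knockout values were 43.6 FPKM in linc-Brn1a and 29.1 FPKM in linc-Enc1 embryos, and its lowest was 0.0660 FPKM in Trp53cor1 adults, in the authors' deposited tables. Cuffdiff tested lacZ in 23 comparisons and called it in 0 of them, with the same behaviour near 0 as for the targets.

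**Figure D1:**
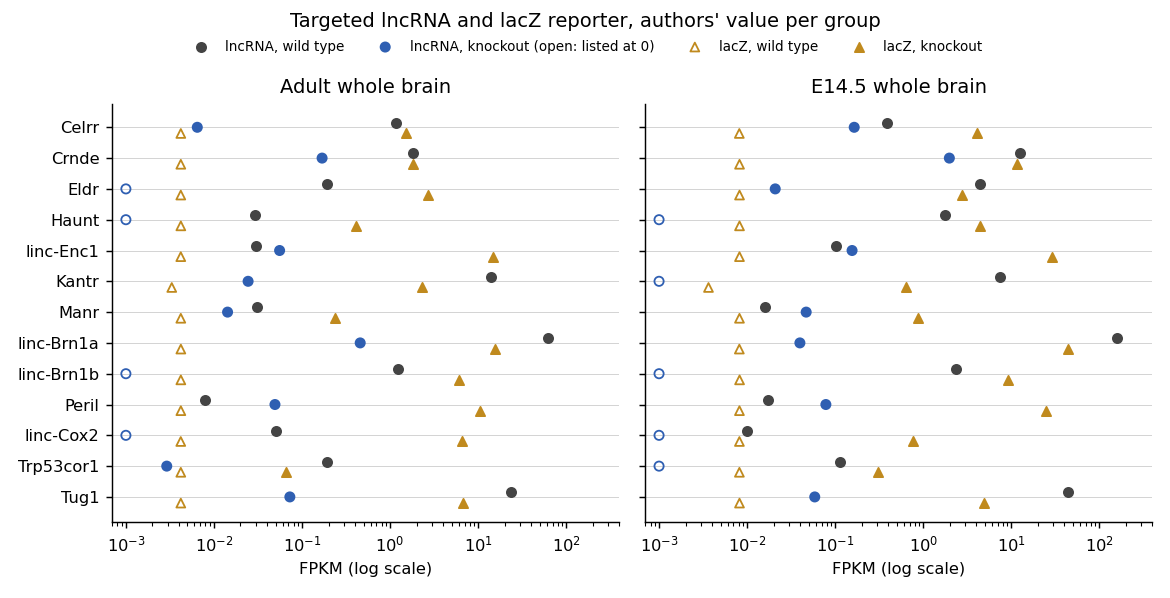
Authors' FPKM value per group (log axis) of the targeted lncRNA (circles) and lacZ (triangles) in wild type and knockout, for 13 strains in adult and E14.5 brain; open blue circles at the left edge mark values listed at 0. lacZ lies at or below 0.00821 FPKM in every wild-type group and at or above 0.0660 FPKM in every knockout group.

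The wild-type levels of the targets differed between the times, as values set side by side from tables normalized separately and without a test. Haunt was listed at 0.0293 FPKM in adult and 1.75 FPKM in embryonic wild-type brain, Eldr at 0.191 and 4.37, and linc-Brn1a at 61.3 and 159 FPKM, per the authors' deposited tables. Celrr was 1.17 in adults and 0.389 in embryos and Kantr 14.1 and 7.52 FPKM in the authors' deposited tables. In all, 8 of the 13 targets had the higher wild-type value in the embryo, and lacZ in the knockouts was higher in the embryo in 10 of 13 strains.

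Cuffdiff called 4468 gene changes over the 26 comparisons, from 15759 to 16071 genes tested in each, and 3873 of the calls (86.7%) were within 2-fold. The strains differed most in the embryo. linc-Brn1a embryos had 654 genes higher and 882 lower, and Kantr embryos 279 higher and 487 lower, while Tug1 embryos had 11 and 9 and linc-Enc1 embryos 3 and 13. In adults the counts ran from 27 in Eldr to 315 in Kantr, with a median of 54 against 86 at E14.5. Trp53cor1 embryos had 0 calls by the authors' Cuffdiff test, where 197 genes had an unadjusted p under 0.05. The smallest p in the tables is 5e-05, which 13 genes reached there, and 16 genes at that value would have been needed for a call at q under 0.05, so the smallest q was 0.0612. When the p-values of all 26 comparisons were adjusted together, 17 genes passed in Trp53cor1 embryos, and at a q under 0.01 no gene passed in 18 of the comparisons, this one among them, since too few genes stood at the smallest p. The same joint adjustment left 797 genes in linc-Brn1a embryos and 462 in Kantr embryos.

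**Figure D2:**
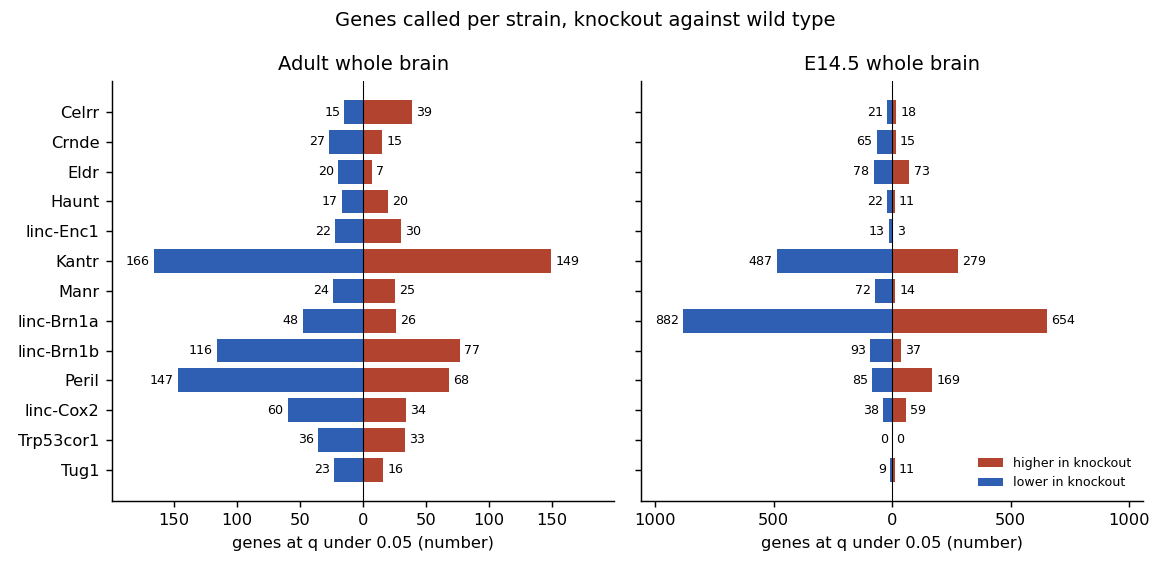
Number of genes at q under 0.05 (horizontal axis, lower in the knockout to the left and higher to the right) for each strain in adult and E14.5 brain, with the number beside each bar; the 2 panels have different scales. linc-Brn1a and Kantr embryos have the longest bars, with 1536 and 766 genes, and Trp53cor1 embryos have 0.

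Near the deleted loci the clearest sets of changes were at Tug1, Trp53cor1 and linc-Enc1. In Tug1 knockouts, Rnf185, an E3 ubiquitin ligase gene, rose from 13.7 to 28.1 FPKM in adults and from 20.1 to 37.5 FPKM at E14.5 in the authors' deposited tables. Inpp5j (a phosphoinositide phosphatase), the processed transcript 8430429K09Rik and Selm (a selenoprotein) rose with it at both times, Selm from 144 to 304 FPKM in adults and from 22.4 to 32.7 FPKM in embryos, per the authors' deposited tables. These 4 genes lie 122 to 187 kb from Tug1 on the side away from Morc2a, whose annotated start is 452 bp from Tug1 and which fell from 12.4 to 7.15 FPKM in adults and from 36.9 to 22.2 FPKM in embryos in the authors' deposited tables. Osbp2, nearer to Tug1 at 54.7 kb, was 11.4 to 17.8 FPKM at E14.5 and did not pass (q = 0.884), per the authors' deposited table. Within 1 Mb of Tug1, 5 of 32 tested genes changed in adults and 5 of 34 in embryos, against 0.214% and 0.0881% of the genes elsewhere (Fisher's exact test, 2-sided, adjusted p = 1.70e-07 and 9.64e-09 over the 26 comparisons). Against the same window in the other 12 strains the adjusted p was 0.00851 and 0.00102.

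In Trp53cor1 adults, Cdkn1a, the gene of the cell-cycle inhibitor p21 that starts 12018 bp from the lncRNA, fell from 20.5 to 0.566 FPKM, the largest fall of any gene called within 1 Mb of a target in the authors' deposited tables. Cpne5, a calcium-dependent membrane-binding protein gene, fell (log2 fold change -0.59) and Ppil1, a spliceosomal isomerase gene, from 9.89 to 7.30 FPKM, while Pi16 rose from 0.491 to 1.02 FPKM in the authors' deposited table. These are 4 of the 35 tested genes in the window (adjusted p = 0.000133 against the rest of the genome and 0.136 against the same window in the other 12 strains, Fisher's exact test). The same window held 11 calls in 426 tests of the other strains in adults. Cdkn1a was also among the genes called in 3 or more strains and rose in Kantr adults, so its level varied with the Trp53cor1 locus intact. At E14.5 Cdkn1a was 13.7 to 3.16 FPKM and Cpne5 12.1 to 7.60 FPKM in the authors' deposited table, and neither passed (q = 0.0612 and 1.00), in a comparison whose number of genes at the smallest p allowed no call. Srsf3, a splicing factor gene 14.1 kb from the lncRNA, was 39.8 to 42.2 FPKM in adults, and the test did not pass (q = 1.00, the authors' deposited table).

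In linc-Enc1 knockouts, Enc1, an actin-binding protein gene of neurons 199 kb from the locus, fell from 132 to 107 FPKM in adults and from 157 to 111 FPKM in embryos in the authors' deposited tables. Gm2373, a lncRNA annotated on the other strand across the linc-Enc1 locus, rose from 0.339 to 1.84 FPKM and from 0.892 to 6.06 FPKM in the authors' deposited tables, and reads of the 2 overlapping genes or of a transcript of the altered allele cannot be separated without strand. The linc-Enc1 window held 2 calls among 20 tested genes at each time (adjusted p = 0.01 in adults and 0.00116 in embryos against the rest of the genome, and 0.0489 and 0.225 against the other 12 strains, Fisher's exact test).

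Single genes changed near other loci. Egfr, the epidermal growth factor receptor gene 16996 bp from Eldr, fell from 2.14 to 0.887 FPKM in embryos and was 2.58 to 1.94 FPKM in adults (q = 1.00), and Fbxo48, an F-box protein gene 93 bp from Eldr, rose from 0.489 to 1.73 FPKM in adults, in the authors' deposited tables. Ptgs2, which encodes the cyclooxygenase COX-2 and lies 51.0 kb from linc-Cox2, fell from 3.10 to 0.976 FPKM in linc-Cox2 adults and was too low for a test in embryos in the authors' deposited tables. The histone demethylase gene Kdm5c, 23965 bp from Kantr, rose from 10.9 to 14.9 FPKM in Kantr adults, where by label 2 of the 3 knockouts were female and all 3 wild-type mice male, in the authors' deposited table. Kdm5c was 20.5 to 28.1 FPKM in embryos and did not pass after adjustment (p = 0.0144), while Gm6472, a short gene model 582 kb away whose reads may be shared with similar copies, fell from 561 to 346 FPKM in the authors' deposited table. The authors' deposited tables also have falls of Lpcat2, a phospholipid acyltransferase gene, in Crnde adults (4.12 to 2.51 FPKM), of Fhl2, a LIM-domain protein gene, in linc-Brn1a embryos (5.21 to 3.24 FPKM), and of Atp11b, a lipid flippase gene, in Peril embryos (29.6 to 22.0 FPKM), at 428 to 972 kb. None of these windows passed the Fisher test. At q under 0.01, Egfr in Eldr embryos and Gm6472 in Kantr embryos were the only genes within 1 Mb of a target still called. Their p of 5e-05 by Cuffdiff is the smallest possible here and is shared by most other genes called near a locus. Their lower q comes from the larger number of genes at that p in their comparisons (88 and 301).

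The genes fixed beforehand as neighbours gave 104 tested measurements on the chromosome of their locus, of which 14 passed. Pou3f3 was 57.3 to 62.6 FPKM in linc-Brn1a embryos and 57.6 to 56.4 FPKM in linc-Brn1b embryos, and Sox2, a stem-cell transcription factor gene 112 kb from Peril, was 63.0 to 56.7 FPKM in Peril embryos, each with q over 0.05 in the authors' deposited tables. Irx5, 1.68 kb from Crnde, was 6.00 to 5.20 FPKM and Hoxa2, near Haunt, 3.99 to 5.09 FPKM in the embryos of those strains, also with q over 0.05 in the authors' deposited tables. Counted over all strains, 26 of 392 tested genes in the knockouts' own windows were called (6.63%), against 56 of 4694 in the same windows of the other strains (1.19%). Dealing the windows to the strains at random gave a mean of 3.16 calls in adults against 15 observed (permutation test, one-sided, p = 4e-05) and 3.15 against 11 at E14.5 (p = 0.00373). The strains come from a cross of different backgrounds, so knockouts and the pooled wild type may carry different alleles near a locus. Such linked alleles could also raise the calls in a strain's own window. The labels give no alleles near the loci, so the window tests cannot separate these alleles from loss of the lncRNA.

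**Figure D3:**
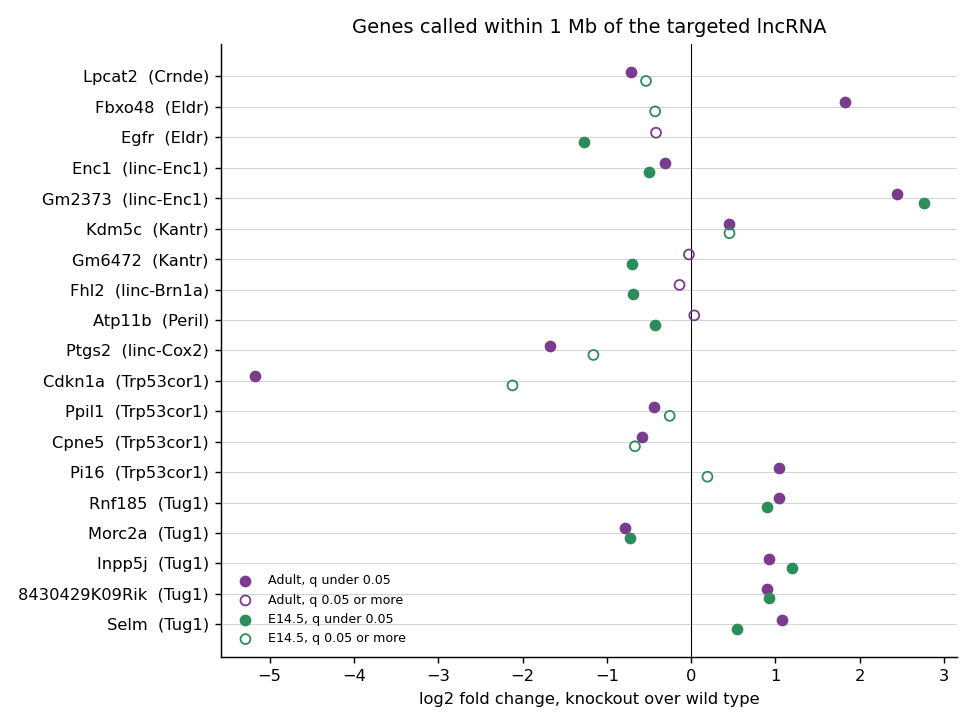
Log2 fold change of the knockout over wild type (horizontal axis) for each gene called within 1 Mb of a targeted lncRNA, with the strain in parentheses, in adults (purple) and at E14.5 (green); filled points have q under 0.05. Cdkn1a in Trp53cor1 adults has the largest fall (-5.18) and Gm2373 in linc-Enc1 embryos the largest rise (2.76).

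For the gene lists fixed beforehand, counts of members that rose or fell are given with the median log2 fold change of the expressed members and its percentile among 10000 random lists of the same size matched on mean expression. The parentheses open with the counts higher and lower when p was adjusted over the list alone. The percentile describes these libraries and is no p-value across mice. Of 1007 such percentiles 462 lay outside the central 95 percent, where independent genes would give 50.4, and the cause of the excess was not tested.

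linc-Brn1a embryos had higher levels of genes of dividing cells and neural progenitors and lower levels of genes of astrocytes, oligodendrocyte precursors, meninges, choroid plexus, striatal neurons, synaptic vesicles and receptors. Of 17 tested proliferation genes 17 rose, 0 fell and 0 did not pass (17 and 0 adjusted over the list alone, median 0.64, percentile 100). Mcm2, a replication helicase subunit, went from 27.5 to 47.8 FPKM and Rrm2, a ribonucleotide reductase subunit, from 34.6 to 62.4 FPKM in the authors' deposited table. Of 12 progenitor genes 7 rose, 2 fell and 3 did not pass (10 and 2 adjusted over the list alone, median 0.37, percentile 100). The stem-cell filament gene Nes rose from 62.9 to 100.1 FPKM in the authors' deposited table. Among 10 genes of intermediate progenitors and newborn neurons 6 rose, 0 fell and 4 did not pass (8 and 0 adjusted over the list alone, median 0.47, percentile 100). The proneural factor gene Neurog1 went from 3.02 to 6.94 FPKM in the authors' deposited table. Among 13 POU and SOX factors 7 rose, 0 fell and 6 did not pass (9 and 0 adjusted over the list alone, median 0.36, percentile 100). Hmga2, a chromatin protein gene of early stem cells, rose from 3.67 to 10.6 FPKM and Foxn4, a progenitor transcription factor gene, from 0.428 to 1.35 FPKM, per the authors' deposited table.

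The lower genes of linc-Brn1a embryos included several tissues. Of 15 genes of meninges and fibroblasts 0 rose, 12 fell and 3 did not pass (0 and 12 adjusted over the list alone, median -0.70, percentile 0). Ptgds, a prostaglandin synthase gene of the meninges, went from 54.0 to 14.9 FPKM in the authors' deposited table. Of 16 choroid plexus genes 1 rose, 10 fell and 5 did not pass (1 and 10 adjusted over the list alone, median -0.71, percentile 0). The transthyretin gene Ttr went from 660.0 to 394 FPKM in the authors' deposited table. Of 11 astrocyte genes 2 rose, 7 fell and 2 did not pass (2 and 8 adjusted over the list alone, median -0.35, percentile 0). Of 8 genes of oligodendrocyte precursors 1 rose, 4 fell and 3 did not pass (1 and 5 adjusted over the list alone, median -0.58, percentile 0.04). Of 15 glutamate and GABA receptor genes 0 rose, 8 fell and 7 did not pass (0 and 10 adjusted over the list alone, median -0.40, percentile 0). The metabotropic receptor gene Grm5 went from 13.3 to 5.90 FPKM in the authors' deposited table. Of 17 synaptic vesicle genes 0 rose, 9 fell and 8 did not pass (0 and 10 adjusted over the list alone, median -0.34, percentile 0). Of 13 striatal neuron genes 0 rose, 6 fell and 7 did not pass (0 and 8 adjusted over the list alone, median -0.69, percentile 0). Among 12 excitatory neuron genes 0 rose, 2 fell and 10 did not pass (0 and 2 adjusted over the list alone, median -0.07, percentile 12.6). Among 15 inhibitory neuron genes 1 rose, 4 fell and 10 did not pass (1 and 4 adjusted over the list alone, median -0.16, percentile 0.11). Of 10 upper-layer genes 2 rose, 3 fell and 5 did not pass (2 and 3 adjusted over the list alone, median 0.15, percentile 93.7). Of 10 deep-layer genes 0 rose, 0 fell and 10 did not pass (0 and 0 adjusted over the list alone, median 0.01, percentile 38.3).

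Blood genes moved with these groups in linc-Brn1a embryos. The embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x rose from 503 to 1334 FPKM, 4.78 to 18.9 FPKM and 29.2 to 101 FPKM, while the adult-type gene Hbb-bs fell from 326 to 236 FPKM and Hba-a2 rose from 54.2 to 78.2 FPKM in the authors' deposited table. Of 11 blood genes 5 rose, 1 fell and 5 did not pass (5 and 1 adjusted over the list alone, median 0.53, percentile 100). Over the 12 strains with the shared cohort, the mean fold change of the 3 embryonic globins and the median of the proliferation list correlated at E14.5 (Pearson's r = 0.874, permutation p = 0.00019, Spearman's rho = 0.867, permutation p = 0.00056, and adjusted p = 0.000380 and 0.000560 over the 2 tests). Without linc-Brn1a and linc-Brn1b, the 2 strains farthest from the median globin change, r was 0.822 over 10 strains (permutation p = 0.00345). The labels give no sequencing batch, and all 12 values share the same wild-type libraries.

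**Figure D4:**
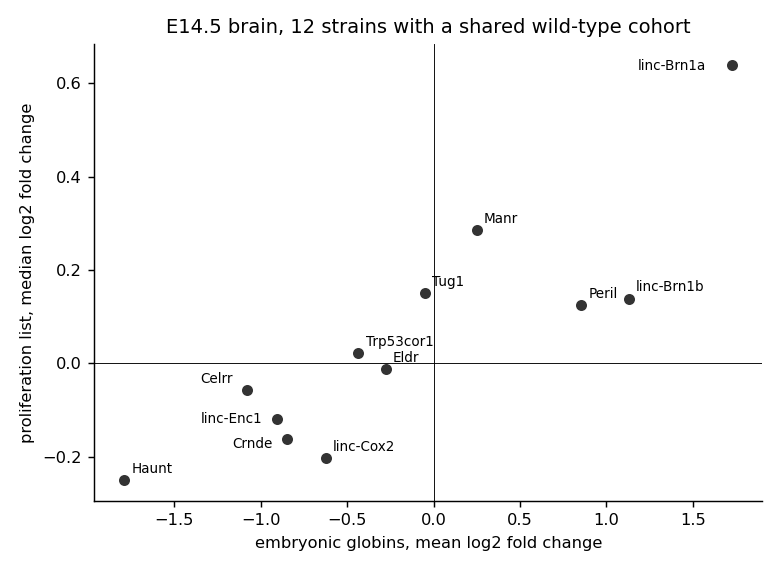
Mean log2 fold change of the embryonic globins Hbb-y, Hbb-bh1 and Hba-x (horizontal axis) against the median log2 fold change of the proliferation list (vertical axis), 1 point for each of the 12 strains compared with the shared wild-type cohort at E14.5. linc-Brn1a is at 1.73 and 0.64 and Haunt at -1.79 and -0.25.

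Immediate early genes, which neurons switch on within minutes of activity, varied in most adult strains. At least 1 was called in 12 of the 13 adult comparisons (55 calls higher and 32 lower) and in 1 comparison at E14.5. In linc-Brn1a adults most of them rose. Of 16 such genes 13 rose, 0 fell and 3 did not pass (13 and 0 adjusted over the list alone, median 0.83, percentile 100). Egr2 went from 2.58 to 6.27 FPKM and Npas4 from 3.35 to 7.93 FPKM in the authors' deposited table. Of 16 genes of heat shock and the unfolded protein response 0 rose, 5 fell and 11 did not pass (0 and 10 adjusted over the list alone, median -0.30, percentile 0). The endoplasmic reticulum chaperone gene Hspa5 went from 172 to 118 FPKM in the authors' deposited table. Both knockout mice were male by label and Xist, the RNA of the inactive X chromosome, went from 29.0 to 0.0818 FPKM in the authors' deposited table.

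linc-Brn1b embryos, which lack a transcript 12.2 kb from linc-Brn1a, had lower levels of genes of cortical and inhibitory neurons. Of 15 inhibitory neuron genes 0 rose, 5 fell and 10 did not pass (0 and 6 adjusted over the list alone, median -0.35, percentile 0). Lhx6, a transcription factor gene of migrating interneurons, went from 14.6 to 7.22 FPKM and Dlx1 from 94.1 to 60.7 FPKM in the authors' deposited table. Of 11 excitatory neuron genes 0 rose, 5 fell and 6 did not pass (0 and 5 adjusted over the list alone, median -0.28, percentile 0). Of 10 deep-layer genes 0 rose, 4 fell and 6 did not pass (0 and 5 adjusted over the list alone, median -0.30, percentile 0). Satb2, a factor of cortical projection neurons, went from 5.71 to 2.79 FPKM and Fezf2 from 18.7 to 13.3 FPKM in the authors' deposited table. The embryonic globin gene Hbb-y rose beside them from 506 to 1114 FPKM, per the authors' deposited table. Of 11 blood genes there 3 rose, 0 fell and 8 did not pass (3 and 1 adjusted over the list alone, median 0.24, percentile 100). By label no wild-type embryo came from the litters of these knockouts, so litter and stage cannot be told apart from loss of linc-Brn1b. The 3 embryonic globins had a mean log2 fold change of 1.13, in the same direction as in linc-Brn1a embryos (1.73). The inhibitory neuron list lay below the central range of its random lists in 6 of 13 comparisons at E14.5 and above it in 3. A lower median of this list was thus not particular to linc-Brn1b. In linc-Brn1b adults 77 genes rose and 116 fell. Of 16 immediate early genes 7 rose, 1 fell and 8 did not pass (9 and 3 adjusted over the list alone, median 0.25, percentile 100). Of 16 heat shock and unfolded protein genes 0 rose, 6 fell and 10 did not pass (0 and 11 adjusted over the list alone, median -0.33, percentile 0). Sgk1, a kinase gene induced by corticosteroids, fell from 72.3 to 35.8 FPKM and Maff, a small Maf factor gene, from 1.92 to 0.589 FPKM in the authors' deposited table.

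Kantr embryos had higher levels of meningeal genes and lower levels of ribosomal, mitochondrial and blood genes than their own wild-type cohort. Among the genes with the largest rises, Hoxa3 and Hoxa2, which pattern the hindbrain, rose from 0.00593 to 2.08 FPKM and 0.310 to 2.99 FPKM, Phox2b, a factor of autonomic and cranial motor neurons, from 0.982 to 4.46 FPKM, Lbx1, a dorsal interneuron factor, from 0.247 to 2.16 FPKM, and Pax2 from 0.613 to 2.95 FPKM in the authors' deposited table. Of 6 Hox A genes 3 rose, 0 fell and 3 did not pass (3 and 0 adjusted over the list alone, median 8.15, percentile 100), a median that rests on genes near 0 in wild type. Of 10 genes of the other Hox clusters 1 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone, median 8.99, percentile 100). Of 6 Irx genes 3 rose, 0 fell and 3 did not pass (3 and 0 adjusted over the list alone, median 0.45, percentile 99.9). Of 15 meningeal genes 11 rose, 0 fell and 4 did not pass (12 and 0 adjusted over the list alone, median 0.71, percentile 100). The collagen gene Col1a1 had a log2 fold change of 1.23 in the authors' deposited table. Of 11 blood genes 0 rose, 6 fell and 5 did not pass (0 and 6 adjusted over the list alone, median -0.57, percentile 0). Hbb-bs went from 688 to 319.7 FPKM in the authors' deposited table. Of 80 ribosomal protein genes 3 rose, 26 fell and 51 did not pass (4 and 43 adjusted over the list alone, median -0.51, percentile 0). Of 74 nuclear genes of oxidative phosphorylation 0 rose, 19 fell and 55 did not pass (0 and 34 adjusted over the list alone, median -0.36, percentile 0). Of 12 mitochondrially encoded genes 0 rose, 6 fell and 6 did not pass (0 and 7 adjusted over the list alone, median -0.73, percentile 0). mt-Co1, a cytochrome oxidase subunit, went from 7751 to 4559 FPKM and Rps5 from 1779 to 1107 FPKM in the authors' deposited table, with reads of ribosomal genes open to sharing with pseudogene copies. Of 15 glutamate and GABA receptor genes 0 rose, 5 fell and 10 did not pass (0 and 7 adjusted over the list alone, median -0.32, percentile 0.01). By label the 3 wild-type embryos and 1 knockout came from 1 litter and the other 2 knockouts from another, so litter is in part mixed with genotype here. The Kantr wild type also lay farther from the N3 wild type (SD 0.433 log2 units) than the Kantr knockouts from the N3 knockouts (0.217). N3 wild-type embryos had 3.54 FPKM of Hoxa3, 3.99 of Hoxa2 and 326 of Hbb-bs, nearer the Kantr knockouts than the Kantr wild type. The changes may thus lie in the wild-type group, the knockouts or both, which was not tested.

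Kantr adults had lower levels of immediate early genes, a list of 16 of which 0 rose, 13 fell and 3 did not pass (1 and 14 adjusted over the list alone, median -0.97, percentile 0). Fos went from 33.7 to 11.4 FPKM, Egr2 from 4.22 to 1.25 FPKM and Btg2 from 14.7 to 5.51 FPKM in the authors' deposited table. In the adult N3 wild type, normalized separately, Btg2 was 6.85 FPKM, nearer the Kantr knockouts than the Kantr wild type. Fos and Egr2 were also lower there than in the Kantr wild type. Of 15 p53 target genes 3 rose, 1 fell and 11 did not pass (5 and 1 adjusted over the list alone, median 0.03, percentile 82.6). Cdkn1a went from 12.3 to 28.5 FPKM in the authors' deposited table, opposite to Btg2, which both lists hold. Of 7 blood genes 1 rose, 3 fell and 3 did not pass (1 and 5 adjusted over the list alone, median -0.52, percentile 0). Gh, the growth hormone gene of the pituitary, fell from 11.8 to 1.08 FPKM in the authors' deposited table. All 4 tested Y genes fell (0 and 4 adjusted over the list alone, median -1.49, percentile 0) and Xist rose from 0.938 to 51.7 FPKM in the authors' deposited table, with 1 male and 2 female knockouts against 3 males by label.

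Peril embryos had higher levels of choroid plexus and meningeal genes and lower levels of inhibitory neuron genes. Of 15 meningeal genes 6 rose, 0 fell and 9 did not pass (11 and 1 adjusted over the list alone, median 0.35, percentile 100). Of 18 choroid plexus genes 4 rose, 0 fell and 14 did not pass (8 and 0 adjusted over the list alone, median 0.39, percentile 100). Of 14 inhibitory neuron genes 0 rose, 6 fell and 8 did not pass (0 and 7 adjusted over the list alone, median -0.36, percentile 0). Dlx2, a factor of the ventral forebrain, fell from 19.8 to 11.6 FPKM, Gad2, which makes GABA, from 25.0 to 17.5 FPKM, and Trpm1, a cation channel gene of retina and pigment cells, rose from 0.259 to 5.04 FPKM in the authors' deposited table. Of 11 blood genes 3 rose, 2 fell and 6 did not pass (3 and 3 adjusted over the list alone, median 0.16, percentile 99.9). Embryonic Hba-x went from 29.3 to 53.8 FPKM and adult-type Hbb-bt from 168 to 128 FPKM in the authors' deposited table. In Peril adults, of 16 immediate early genes 8 rose, 2 fell and 6 did not pass (11 and 4 adjusted over the list alone, median 0.32, percentile 100). Of 16 heat shock and unfolded protein genes 0 rose, 8 fell and 8 did not pass (0 and 12 adjusted over the list alone, median -0.34, percentile 0). Plin4, a lipid droplet coat gene, fell from 1.56 to 0.254 FPKM, Hif3a from 1.87 to 0.609 FPKM and Xist from 29.0 to 0.0160 FPKM in the authors' deposited table. That Xist value is at odds with the labels, which give 2 male and 1 female knockout, and the Y gene Ddx3y rose from 13.7 to 22.8 FPKM in the authors' deposited table.

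linc-Cox2 and Manr knockouts had few changes that fell into a list. In linc-Cox2 adults Tnni1, the slow troponin I gene, fell from 5.85 to 0.335 FPKM and Mcm6 from 2.90 to 0.652 FPKM, while Arhgap27 rose from 9.01 to 31.0 FPKM in the authors' deposited table. Of 16 immediate early genes 4 rose, 0 fell and 12 did not pass there (9 and 3 adjusted over the list alone, median 0.21, percentile 100). Of 16 heat shock and unfolded protein genes 0 rose, 3 fell and 13 did not pass (0 and 8 adjusted over the list alone, median -0.22, percentile 0). In linc-Cox2 embryos Atp6v0c, a proton pump subunit gene, fell from 26.3 to 5.45 FPKM and Arhgap27 rose from 2.23 to 16.7 FPKM in the authors' deposited table. Of 15 meningeal genes there 0 rose, 4 fell and 11 did not pass (0 and 7 adjusted over the list alone, median -0.32, percentile 0). In Manr adults Pomc, the gene of the ACTH precursor, rose from 2.41 to 32.3 FPKM, Tshb, a thyrotropin subunit gene, from 0.236 to 2.89 FPKM, and Fos from 17.7 to 27.2 FPKM in the authors' deposited table. Pomc and Tshb belong to the pituitary list, and of its 9 tested genes 2 rose, 0 fell and 7 did not pass (3 and 0 adjusted over the list alone, median 5.42, percentile 100). Of 16 immediate early genes in Manr adults 6 rose, 0 fell and 10 did not pass (11 and 2 adjusted over the list alone, median 0.31, percentile 100). In Manr embryos 14 genes rose and 72 fell, among them Ptgds from 54.2 to 21.6 FPKM and Olig1, an oligodendrocyte lineage factor gene, from 11.3 to 5.75 FPKM in the authors' deposited table. Of 14 glutamate and GABA receptor genes 0 rose, 3 fell and 11 did not pass (0 and 6 adjusted over the list alone, median -0.25, percentile 0).

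Haunt, Celrr, Crnde, linc-Enc1 and linc-Cox2 embryos had lower Hbb-y, the opposite of linc-Brn1a embryos. Hbb-y fell from 505 to 139 FPKM in Haunt, from 503 to 269 FPKM in Celrr, from 505 to 266 FPKM in Crnde, from 505 to 304 FPKM in linc-Enc1 and from 504 to 314 FPKM in linc-Cox2 embryos in the authors' deposited tables. Hba-x, the other embryonic globin gene called in Celrr embryos, fell there from 29.2 to 13.1 FPKM in the authors' deposited table, and of 11 blood genes 0 rose, 2 fell and 9 did not pass (2 and 4 adjusted over the list alone, median -0.49, percentile 0). Of 11 blood genes 0 rose, 3 fell and 8 did not pass in Haunt (0 and 4 adjusted over the list alone, median -0.40, percentile 0). In Crnde embryos, of 11 blood genes, 0 rose, 3 fell and 8 did not pass (0 and 3 adjusted over the list alone, median 0.01, percentile 59.1), and of 11 in linc-Enc1 embryos 0 rose, 3 fell and 8 did not pass (0 and 6 adjusted over the list alone, median -0.38, percentile 0). Of 15 inhibitory neuron genes in Haunt embryos 0 rose, 3 fell and 12 did not pass (0 and 3 adjusted over the list alone, median -0.14, percentile 0). Dlx2 went from 19.8 to 13.2 FPKM in the authors' deposited table. Of 15 meningeal genes in Crnde embryos 0 rose, 4 fell and 11 did not pass (1 and 4 adjusted over the list alone, median -0.23, percentile 0). Col1a1 went from 24.9 to 14.7 FPKM in the authors' deposited table. Of 16 immediate early genes in Haunt adults 8 rose, 0 fell and 8 did not pass (12 and 0 adjusted over the list alone, median 0.41, percentile 100), and of 16 in Crnde adults 0 rose, 9 fell and 7 did not pass (1 and 13 adjusted over the list alone, median -0.55, percentile 0). Arc, a synaptic plasticity gene, went from 41.4 to 69.0 FPKM in Haunt and from 41.4 to 25.9 FPKM in Crnde in the authors' deposited tables. In linc-Enc1 adults the genes with the largest rises included Obp1a, an odorant-binding protein gene, from 0.892 to 80.9 FPKM, Obp2a from 1.08 to 49.7 FPKM and the major urinary protein gene Mup4 from 0.294 to 45.9 FPKM in the authors' deposited table.

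Celrr, Eldr, Trp53cor1 and Tug1 completed the set. In Celrr adults, of 16 immediate early genes 7 rose, 0 fell and 9 did not pass (11 and 0 adjusted over the list alone, median 0.31, percentile 100). Of 16 heat shock and unfolded protein genes 8 rose, 0 fell and 8 did not pass (12 and 0 adjusted over the list alone, median 0.35, percentile 100). Hspa5 went from 172 to 221 FPKM in the authors' deposited table. Of 80 ribosomal protein genes in Celrr embryos 7 rose, 0 fell and 73 did not pass (16 and 0 adjusted over the list alone, median 0.29, percentile 100). The hindbrain gene Phox2b fell from 4.25 to 1.95 FPKM in the authors' deposited table. In Eldr adults, of 16 immediate early genes 0 rose, 6 fell and 10 did not pass (0 and 15 adjusted over the list alone, median -0.42, percentile 0). Egr2 went from 2.58 to 1.21 FPKM in the authors' deposited table. Of 15 meningeal genes in Eldr embryos 0 rose, 4 fell and 11 did not pass (0 and 5 adjusted over the list alone, median -0.17, percentile 0). Ndufs5, a subunit gene of respiratory complex I, fell from 25.1 to 0.701 FPKM in the authors' deposited table. Trp53cor1 adults had lower Atp6v0c, from 59.5 to 10.4 FPKM, and Hmga1, a chromatin protein gene, from 6.15 to 1.75 FPKM, in the authors' deposited table. Of 15 p53 target genes 0 rose, 1 fell and 14 did not pass (0 and 1 adjusted over the list alone, median -0.01, percentile 37), the lower gene being Cdkn1a. The fall of Atp6v0c was not particular to Trp53cor1, since Atp6v0c also fell in linc-Cox2 adults and embryos. Alleles linked to the locus beyond 1 Mb were not tested as a source of such calls. Apart from its window, Tug1 embryos had falls of Eno1, a glycolytic enzyme gene, from 43.7 to 21.8 FPKM, and of Lyz2, a lysozyme gene of myeloid cells, from 8.21 to 4.52 FPKM in the authors' deposited table.

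**Figure D5:**
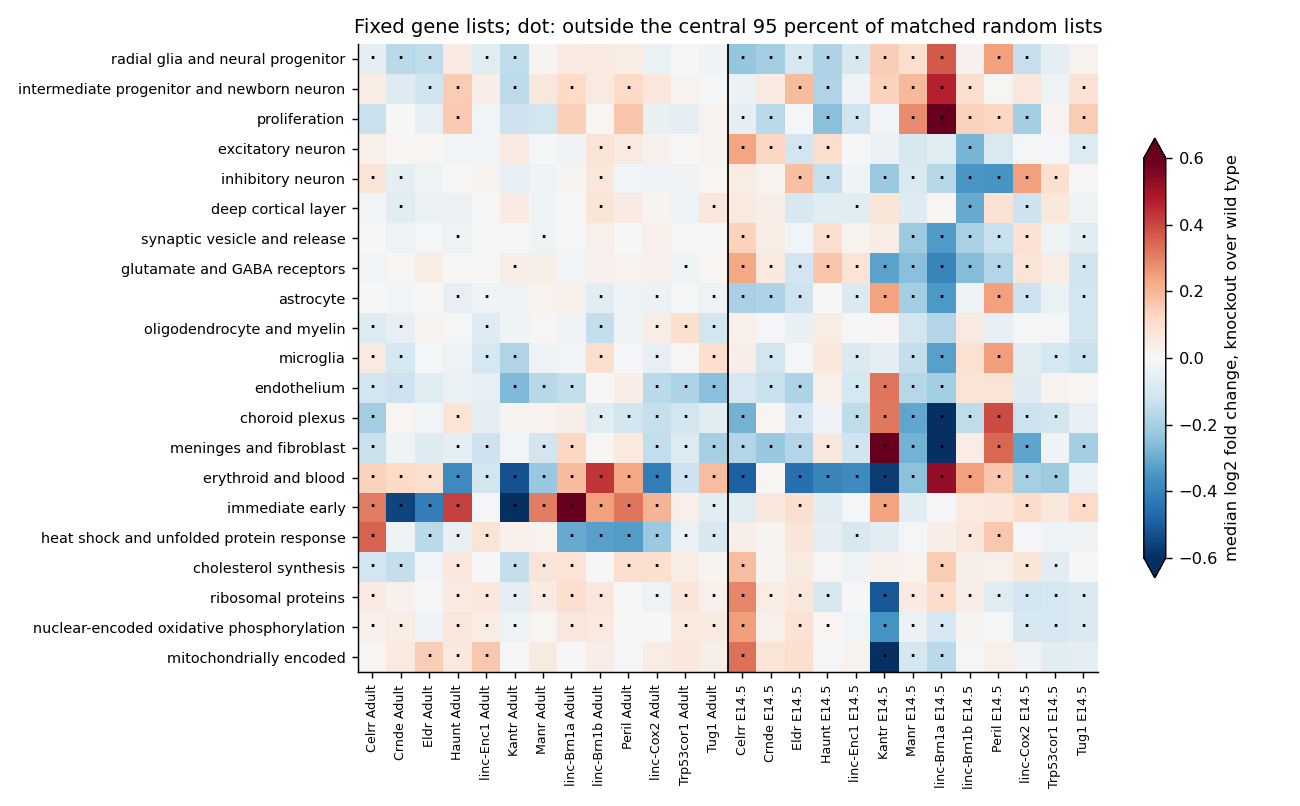
Median log2 fold change of the knockout over wild type (color, from -0.6 to 0.6, values beyond these drawn at the end colors) for 21 fixed gene lists in the 26 comparisons, adults to the left of the line and E14.5 to the right; a dot marks a median outside the central 95 percent of matched random lists. Immediate early genes range from -0.97 (Kantr) to 0.83 (linc-Brn1a) in adults, and proliferation genes reach 0.64 in linc-Brn1a embryos.

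Some strains had calls in common between adult and embryonic brain, which share no libraries. linc-Cox2 had the most genes called at both times in the same direction, 18 of 22 shared. Independent lists gave 0.534 shared genes, in either direction, against these 22 (Fisher's exact test, adjusted p = 2.91e-29 over 12 strains). The 18 included Arhgap27, the protease gene Prss41 and Wdfy1, all higher at both times, and Atp6v0c, Mcm6 and Hddc3, lower at both. Some of these are not particular to linc-Cox2. Wdfy1 was also higher at both times in Eldr, Manr and linc-Brn1b, and Hddc3 was called at both times in several other strains. Arhgap27 was called at both times in Manr, in opposite directions. Atp6v0c also fell in Trp53cor1 adults. linc-Cox2 and Trp53cor1 adults shared 22 calls in the same direction and 1 in the opposite, where simulated unchanged groups gave 0.9 in the same direction. The overlap was not tested without genes called in many strains. Alleles fixed within a strain would also be present at both times, so the overlap cannot separate them from loss of the lncRNA. In Tug1 8 genes were called at both times, 7 of them in the same direction, and 2 were left, 1 in the same direction, without sex-linked genes and genes within 1 Mb. In linc-Enc1 5 genes were shared and 4 went the same way, Enc1 and Gm2373 among them. Peril shared 22 genes with 9 in the same direction, Kantr 27 (13.6 by independent lists) with 14 in the same direction, and linc-Brn1a 18 (6.67 by independent lists) with 10, so about as many of these went opposite ways. The overlap passed the Fisher test in 11 of the 12 strains with calls at both times, Celrr being the exception (1 shared gene, adjusted p = 0.110).

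Between strains at a time point, fold changes correlated across genes, which are not independent replicates. The 66 pairs of strains that share the N3 cohort had a median r of 0.27 in adults, where unchanged groups simulated against the same cohort gave 0.15, and 0.24 against 0.18 at E14.5. The median covariance was 0.00848 against 0.00441 given by the shared cohort in adults and 0.0104 against 0.00674 at E14.5. Pairs of those strains with Kantr, which has its own cohort, had a median r of 0.01 in adults and -0.02 at E14.5. Calls shared in those pairs with Kantr went the same way 113 times and opposite ways 263 times in adults, and 210 and 232 times at E14.5. In the 66 pairs that share the N3 cohort, calls shared in the same direction numbered 744 in adults and in opposite directions 341, where the simulation gave 46.2 and independent lists of the same sizes 12.4. At E14.5 the numbers were 567 and 405 against 159.1 and 54.7. With group values alone the cohort could not be split, so part of the excess may come from the shared controls. The simulation drew genes independently and with equal spread. It can therefore understate the calls shared without change where genes vary together or more than others.

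Among the 12 strains with the N3 cohort, genes called in 3 or more strains in one direction numbered 68 in adults and 90 at E14.5, where independent lists gave 0.092 and 0.606 and a simulated shared cohort with nothing changed 2.58 and 10.2. AA465934, an unnamed transcript, was lower in 11 strains and higher in 1 in adults, between 4.32 and 61.1 FPKM in the knockout groups against 13.3 FPKM in wild type in the authors' deposited tables. The separate wild-type cohort of Kantr had 4.08 FPKM of AA465934 in the authors' deposited table and its knockouts 4.82 FPKM, near the median of 5.12 FPKM over the N3 knockout groups and unlike the N3 wild type. Hddc3, a phosphohydrolase gene, was lower in 9 and higher in 2, Nes lower in 9 and higher in 0, Adi1, an enzyme gene of methionine salvage, lower in 9 and higher in 1, and Fos higher in 7 and lower in 2. Hddc3 was at 18.3 FPKM in the N3 wild type, a median of 11.8 FPKM in the knockout groups and 12.5 FPKM in the Kantr wild type in the authors' deposited tables, with Adi1 at 34.2, 23.4 and 21.3 FPKM and Nes at 2.83, 2.01 and 2.33 FPKM. None of AA465934, Hddc3, Adi1 and Nes passed in Kantr adults (q = 0.999). At E14.5 Hddc3 was lower in 7 strains and higher in 2, Hbb-y higher in 3 and lower in 5, Wdfy1 higher in 5 and lower in 1, and the matrix genes Fn1 and Col1a1 each lower in 5 and higher in 1. Of the 68 and 90 genes, 36 and 48 were called in both directions in different strains. Without linc-Brn1a, 46 genes remained at that threshold at E14.5.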

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

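A gene near a locus was marked for a closer look where its change differed between adult and embryonic brain, a test chosen after the changes at each time had been seen. The standard error (SE) of the difference was derived from the authors' p by a normal approximation and the p adjusted over 53 genes. Fbxo48 in Eldr had an adult minus E14.5 log2 fold change of 2.25 (SE 0.505, adjusted p = 0.000449), from 0.489 to 1.73 FPKM in adults and 2.05 to 1.53 FPKM in embryos in the authors' deposited tables. Gm6472 in Kantr differed by 0.67 (adjusted p = 0.0137), its fall standing in embryos alone. Atp11b in Peril differed by 0.47 (adjusted p = 0.0137), also with its fall in embryos. The derived SE is an upper bound only where p is at its smallest value of 5e-05, as for Fbxo48 in adults and Gm6472 in embryos, and for Atp11b it is a plain approximation at both times.

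The first pattern weighed is the set of 1536 calls in linc-Brn1a embryos, with its test of adult-type globins chosen after the result was seen and the other 2 set before their value was computed but after the list directions were known. Fold changes fell with the adult over embryonic wild-type ratio (Spearman's rho = -0.47 over 13931 genes), which fits knockout embryos at an earlier stage than the wild-type cohort, although fold and ratio share the embryonic wild-type value, which pushes this correlation toward positive values. The embryonic globins followed the proliferation list across strains (Pearson's r = 0.874, permutation p = 0.00019), which fits the same reading. Adult-type globins had a mean log2 fold change of 0.00606, below the level set for more blood in the tissue. That mean joins higher Hba-a2 (0.53) and Hba-a1 (0.13) with lower Hbb-bs (-0.47) and Hbb-bt (-0.16), so it cannot decide on the amount of blood. No wild-type embryo comes from the same litters, so stage and loss of linc-Brn1a cannot be told apart here. Manr (rho = -0.45) and linc-Brn1b (-0.25) embryos had the next lowest values and Haunt embryos (0.36) the highest.

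The second pattern is the rise of Kdm5c in Kantr adults, with its test of escape genes chosen after the result was seen and its test of the share set before. The median log2 fold change of 5 other genes that escape X inactivation was 0.279, which fits the larger number of females among the knockouts. The sex difference of Kdm5c in the other strains gives 0.38 (SE 0.083) of the 0.45 seen, a share of 0.837, and without Peril adults and Celrr embryos, whose sex-linked genes differ from their labels, a share of 0.83. At E14.5 the escape genes had a median of -0.17 while Kdm5c had 0.46 (p = 0.0144), so the escape genes were not higher there.

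The third pattern is the set of genes called in 3 or more strains, with its tests in Kantr chosen after the result was seen. Kantr, which has its own cohort, called 35 of the 63 adult genes tested there (55.6 percent; Fisher's exact test, p = 5.44e-44, against 1.72 percent of other genes) and 30 of 87 at E14.5 (34.5 percent, p = 2.45e-18, against 4.65 percent). Its wild type lay on the knockouts' side of the N3 wild type for 82.5 percent of the adult set against 60.6 percent of other genes (Fisher's exact test, p = 0.000246), AA465934, Hddc3 and Adi1 among them. At E14.5 it did so for 58.6 percent against 59.5 percent (Fisher's exact test, p = 0.913). Of the Kantr calls in the set, 6 went the way of most N3 calls and 26 the opposite way in adults (sign test, p = 0.000535), so most adult calls do not repeat the N3 changes. At E14.5 the numbers were 12 and 17, not distinct from an even split (sign test, p = 0.458). In adults, chance values of the N3 cohort and changes in the knockouts cannot be told apart. At E14.5 the set was called more often in Kantr and the Kantr wild type was not shifted, but the Kantr calls had no shared direction with N3. Genes picked for calls in several strains were not matched with the other genes. The higher share therefore cannot decide between these readings at E14.5. Alleles fixed within a strain would make adult and embryonic changes agree across strains. The median Spearman correlation was -0.0315 (percentile 28.1 among matched genes), so the set did not have such agreement, while single genes such as Wdfy1 (0.769), Adi1 (0.678) and AA465934 (0.594) did. Alleles that vary between mice of a strain need not give agreement, since the times use different mice, and the set holds genes called at only 1 time. The test therefore cannot exclude segregating alleles.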

How the results depend on the processing

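No paired analysis was possible because the deposited tables hold 1 value per group and no value per library. For the same reason these were not run: leaving each knockout replicate out, a pseudocount of 0.1 in a fit per library, sex as a covariate, a sex-matched wild type or all groups in 1 fit, the tool limma, and litter as a replicate block. No result reversed its direction. Of 1007 list medians, 949 were the same over all tested members, 996 after centring and 980 with a pseudocount of 1 FPKM. Leaving out genes under 1 FPKM, sex-linked genes or the window left all 26 counts on their side, and the depth of the libraries, which limits low genes such as most targets, is unknown.

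Adjusted over all 26 comparisons together, genes called numbered 49 in Eldr adults and, at E14.5, 51 in Haunt, 462 in Kantr, 797 in linc-Brn1a, 17 in Trp53cor1 and 34 in Tug1, where the number of genes at the smallest p sets the threshold. With an absolute log2 fold change of 1 or more, adult and E14.5 calls were 8 and 11 in Celrr, 8 and 7 in Crnde, 7 and 32 in Eldr, 4 and 10 in Haunt, 20 and 6 in linc-Enc1, 60 and 98 in Kantr, 11 and 7 in Manr, 12 and 145 in linc-Brn1a, 17 and 16 in linc-Brn1b, 30 and 19 in Peril, 18 and 18 in linc-Cox2, 10 and 6 in Tug1, and 15 in Trp53cor1 adults, since most calls are within 2-fold.

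At q under 0.01, genes called numbered 88 in Eldr embryos, 201 in Kantr adults, 407 in Kantr embryos, 841 in linc-Brn1a embryos, 119 in linc-Brn1b adults, 91 in linc-Brn1b embryos, 136 in Peril adults and 121 in Peril embryos. They were 0 in Celrr, Crnde, Haunt, linc-Enc1, Manr, linc-Cox2, Trp53cor1 and Tug1 at both times and in Eldr and linc-Brn1a adults, by construction of the smallest p. At that threshold the calls near the locus became 0 for linc-Enc1 and Tug1 at both times, for Trp53cor1, Crnde, Eldr, Kantr and linc-Cox2 adults and for linc-Brn1a and Peril embryos, and 1 each stayed in Eldr and Kantr embryos. Calls shared between strains in the same direction became 56 in adults and 81 at E14.5, and genes called in 3 or more strains 0 and 5. For Crnde adults the window reached 2 called genes at 2 Mb and held 1 at 500 kb, both then passing the test, and the cause was not tested. Without linc-Brn1a, 46 genes were called in 3 or more strains at E14.5.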

Other observations

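Some genes known to be induced by glucocorticoids were called in adult strains, and they were chosen after the values were seen, with no list fixed and no test of the group. In Kantr adults the immunophilin gene Fkbp5 rose from 11.3 to 26.9 FPKM, the zinc finger factor gene Zbtb16 from 4.50 to 12.9 FPKM, Sgk1 from 42.8 to 87.8 FPKM and Tsc22d3, which encodes the leucine zipper protein GILZ, from 54.6 to 83.0 FPKM in the authors' deposited table. Plin4 and Hif3a rose there too, from 0.415 to 3.42 FPKM and 0.901 to 3.99 FPKM in the authors' deposited table, and both fell in Peril adults. Sgk1 fell in linc-Brn1b adults from 72.3 to 35.8 FPKM, per the authors' deposited table, and over the 12 strains with the N3 cohort Sgk1 and Zbtb16 were each lower in 4 and higher in 0, and Fkbp5 and Tsc22d3 each lower in 3 and higher in 1. Those 12 strains share their wild-type libraries. Sgk1, Plin4 and Hif3a were lower in the Kantr wild type than in the N3 wild type, normalized separately (Sgk1 42.8 against 72.3 FPKM). Their rises in Kantr may thus lie in the wild-type group, the knockouts or both, which was not tested.

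Sex-linked genes differ from the labels most clearly in 2 knockout groups. Celrr embryos are labelled as 1 male and 2 females, and the Y genes Ddx3y and Eif2s3y went from 8.06 and 36.6 FPKM to values listed at 0, while Xist went from 113 to 249 FPKM, in the authors' deposited table. Peril adults are labelled as 2 males and 1 female, and Xist was 29.0 to 0.0160 FPKM in the authors' deposited table. Trp53cor1 embryos are labelled as 1 male and 2 females, against 7 males and 7 females in the wild type. Their Y genes were not below the wild type, with Ddx3y at 8.08 to 8.35 FPKM and Kdm5d at 6.24 to 8.51 FPKM, and none passed the test.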
